A study of Homo sapiens with 27 samples.

How the data were processed

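Polyadenylated RNA was sequenced from retinal pigment epithelium (RPE, the pigmented layer that supports the photoreceptors) differentiated in culture from the established human induced pluripotent stem cell line IMR90-4. Per the labels, RNA was extracted with Trizol, its quality was checked on an Agilent BioAnalyzer, and low-input poly-A libraries were made for the BGISEQ-500 platform. The labels describe 27 libraries in 9 groups of 3. In a time course, 15 libraries of wild-type cells were untreated or had received C1QTNF5 (also called CTRP5, a secreted C1q and tumour necrosis factor related protein) for 2, 4, 6 or 8 h. In a second experiment, called the knockout experiment here, 12 libraries were labelled wild type or MFRP knockout and untreated or treated with C1QTNF5 for 4 h. MFRP encodes a membrane frizzled-related protein of the RPE.

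Per the file headers, the authors deposited FPKM values (fragments scaled by transcript length and by the mapped fragments of the library) for each gene and library in 1 table per experiment, printed to 2 decimals. The submitters' processing notes name Bowtie2, HISAT and the build GRCh37 without versions or roles. The quantifier, the annotation release and any scaling between libraries are not stated. The tables hold 20615 genes for the time course and 20695 for the knockout experiment, with gene identifiers from Entrez Gene. Symbols were looked up by these identifiers, of which 99.3% matched in each table. Gene positions are not given, because the reference at hand is of another build than the one the notes name. Neither read totals nor counts are in the tables, so the total depth of each library is unknown, and no counting interval or detection floor is given. Relative depth was estimated from the steps between low FPKM values of genes with 1 transcript, with 100 nt taken off its length. It ran from 0.896 to 1.22 times the median library in the time course and from 0.81 to 1.18 times in the knockout experiment.

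Values were analysed as log2(FPKM + 1). Genes with an FPKM of at least 1 in at least 3 libraries of an experiment were tested, which kept 14706 genes in the time course and 15090 in the knockout experiment. The pseudocount pulls the fold changes of genes with an FPKM near or under 1 towards 0, so their values understate the ratio of the means. For each experiment, 1 linear model with a term per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend of the spread on the mean). P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, and an adjusted p under 0.05 counted as a change. Errors of log2 fold changes are moderated standard errors (SE), and errors of FPKM means are standard deviations (SD) over 3 libraries. The 2 tables were tested only separately, since nothing states that they were scaled together.

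The comparisons were each treatment time against untreated, 8 h against 2 h, a moderated F-test over the 4 times, knockout against wild type without and with C1QTNF5, treatment against no treatment in each labelled genotype, and the difference between these treatment responses (the interaction). The comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. A pair of contrasts was added later: the mean of both treatment responses, and the mean of both genotype differences. Of 44 lists of genes (pathways, cell functions and markers of RPE and of other cell types), 43 had at least 5 tested members in each experiment. The list of mitochondrially encoded genes could not be tested, as 0 of its members are in the tables. Lists were tested with camera in limma, which compares the members with all other tested genes, at a preset correlation between genes of 0.01. P-values were adjusted over the lists of a comparison, and each list was tested again with a correlation estimated from the libraries. Counts of changed members are given as adjusted over all genes and as adjusted over the list alone.

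Genes were named by rule. In each comparison these were the 10 largest increases and the 10 largest decreases among genes with an adjusted p under 0.05, a mean FPKM of at least 2 in 1 of the groups and no overlap between the libraries of both groups, so each lay higher or lower in 3 of 3 libraries. No separation was asked for the interaction. Symbols beginning with LOC, LINC, MIR, SNOR or RNU, symbols holding orf or -AS, XIST and Y-linked genes were passed over. MFRP and C1QTNF5 were named in every comparison, along with up to 4 members of smallest p in each list described. The levels of MFRP and C1QTNF5 were also compared by exact two-sided permutation tests, whose smallest possible p with 3 against 3 libraries is 0.1.

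Alternatives covered pseudocounts of 0.1 and 0.5, no filter, a filter at an FPKM of 5, median-ratio scaling and quantile normalization, fits on the compared groups only, eBayes without the trend, array weights, the sample number as a replicate block, and leaving out each library in turn. A test on counts was not run, since the tables hold none. Exchanging the genotype labels of the treated libraries was added after seeing the data. The labels do not say that samples of 1 number belong together across groups. Residuals of libraries with the same number correlated at a mean of 0.013 in the time course and 0.031 in the knockout experiment. For different numbers the means were -0.0064 and -0.016. Correlation was best with the own number for 6 of 15 and 9 of 12 libraries. As these correlations were small, samples were treated as unpaired, but a weak pairing in the knockout experiment is not excluded. Nothing states that replicates are separate cultures, so the p-values measure only the spread between these samples. The pipeline was tested on simulated data with 200 changed genes for each of 9 comparisons between groups. It recovered 61.2% to 83.6% of genes changed 1.5-fold, 85.1% to 100% at 2-fold and 98.5% to 100% at 4-fold, and 2.66% to 6.42% of its calls were false. The simulated noise was normal and independent between genes, and the changed genes had a baseline FPKM over 2. These shares therefore need not hold for correlated genes or for genes near the filter. Figures and auxiliary checks used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.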

Results

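RNA was measured in 27 libraries of human iPSC-derived RPE, in 9 groups of 3. The time course held wild-type cells that were untreated or had received C1QTNF5 for 2, 4, 6 or 8 h. The knockout experiment held cells labelled wild type or MFRP knockout, each untreated or treated for 4 h. The number of genes at an FPKM of at least 1 ran from 13414 to 14063 per library in the time course and from 14281 to 15004 in the knockout experiment. Replicates of a group correlated at 0.972 to 0.985 across genes in the time course and at 0.935 to 0.986 in the knockout experiment. The lowest values came from treated knockout replicate 1, whose FPKM sum of 350897 lay under the 397365 to 422170 of the other 11 libraries of that experiment. The ribosomal RNA gene RNA28SN5 was at 53.2 FPKM in that library and at 1.09 to 2.54 FPKM in the other 11. In the time course RNA28SN5 was at 591 to 1540 FPKM. Nothing states that the experiments were scaled together, but the FPKM sums of the time course were 433122 to 472826. A difference in scaling would shift the sums too, so it does not account for this gap, whose cause was not tested. The labels name no vehicle-treated or time-matched control, so each treated group was compared with untreated cells of the same experiment. Effects of handling or of the time elapsed cannot be told apart from those of C1QTNF5 in these comparisons.

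The 2 h comparison addressed the first transcripts to change after C1QTNF5. Immediate-early genes, which are transcribed soon after an extracellular signal, rose together, with 36 of 36 measured members higher (36 adjusted over the list alone) and a median log2 fold change of 2.16. Members low without treatment could pass the filter through treated libraries alone, which can raise this share. The transcription factor gene EGR1 (Entrez Gene 1958) rose from 2.08 ± 0.39 to 119.5 ± 19.1 FPKM (SD, n = 3), a log2 fold change of 5.29 ± 0.16 (SE). The AP-1 genes FOSB and FOS rose by 4.68 ± 0.13 and 4.03 ± 0.13 on the log2 scale, and the transcriptional repressor gene KLF10 by 3.18 ± 0.10. The list passed camera with an adjusted p = 1.1e-78, and with an adjusted p = 0.00356 with an estimated correlation. ARC, DUSP5, EGR2 and NR4A1, also in this list, were among the 10 largest increases, at log2 fold changes of 3.44 to 4.61.

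Metal-binding metallothionein genes and their zinc exporter SLC30A1 formed another early group at 2 h. Of 9 measured members 6 rose (6 adjusted over the list alone), with a median log2 fold change of 2.03 (adjusted p = 2.2e-07, and adjusted p = 0.251 with an estimated correlation). MT1X rose from 17.8 ± 2.12 to 313 ± 198 FPKM, with a wide spread between the treated libraries, and SLC30A1 by 2.03 ± 0.16 on the log2 scale. Glucocorticoid-responsive genes rose in 7 of 11 members (8 higher and 1 lower adjusted over the list alone), among them DUSP1 by 1.94 ± 0.11 and the clock gene PER1 by 2.24 ± 0.15 (adjusted p = 0.00544 with an estimated correlation). This list shares MT1X and MT2A with the metallothioneins, DUSP1 with the immediate-early list and PER1 with the clock list. Genes of NF-kB signalling and inflammation rose in 6 of 13 (8 adjusted over the list alone), led by the cytokine gene LIF at 3.62 ± 0.16 and the NF-kB subunit gene RELB at 1.70 ± 0.19 (adjusted p = 0.0122 with an estimated correlation). Targets of p53 rose in 7 of 17 (8 higher and 1 lower adjusted over the list alone), including the cell cycle inhibitor gene CDKN1A by 1.40 ± 0.16 (adjusted p = 0.023 with an estimated correlation). Hypoxia-responsive genes rose in 9 of 21 and fell in 1 (13 and 1 adjusted over the list alone), with NDRG1 up by 1.04 ± 0.21 and DDIT4 down at -0.98 ± 0.11 (adjusted p = 0.0122 with an estimated correlation). Glycolysis genes rose in 7 of 21 (9 adjusted over the list alone), with PFKFB3 up by 1.02 ± 0.16 (adjusted p = 4.4e-06, and adjusted p = 0.273 with an estimated correlation). The glycolysis and hypoxia lists share HK2, PFKFB4 and SLC2A1. Ribosomal protein genes had a median of -0.26, but 2 of 72 passed the test alone (0 adjusted over the list alone), and the list's adjusted p = 9.5e-14 became an adjusted p = 0.673 with an estimated correlation.

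The largest decrease at 2 h was in SOCS3, an inhibitor of cytokine signalling, from 13.7 ± 1.51 to 3.40 ± 0.51 FPKM. The homeobox gene GSX2 fell from 29.8 ± 2.70 to 12.8 ± 1.39 FPKM and the thioredoxin-binding protein gene TXNIP from 81.3 ± 3.44 to 43.8 ± 14.2 FPKM. In all, 1375 genes changed at 2 h, of which 854 rose and 521 fell. This count was 519 when only the 6 libraries compared were fitted, and 909 without untreated replicate 2.

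At 4 h, the largest increase was in TM4SF1 (Entrez Gene 4071), a membrane protein gene of the tetraspanin-like family, from 10.3 ± 2.25 to 278 ± 43.6 FPKM (SD, n = 3), a log2 fold change of 4.63 ± 0.27. The Wnt antagonist gene DKK1 rose by 4.19 ± 0.27, the pentraxin gene PTX3 by 3.91 ± 0.20, and TNFRSF12A, the receptor of the cytokine TWEAK, from 21.6 ± 5.51 to 279 ± 19.3 FPKM. Immediate-early genes were still higher in 28 of 36 and lower in 1 (29 and 1 adjusted over the list alone), with a median of 1.10 (adjusted p = 9e-19, and adjusted p = 0.124 with an estimated correlation). Within this list, FOSL1, DUSP6, SPRY2 and SPRY4 rose by 2.48 to 3.49 on the log2 scale. NF-kB and inflammation genes rose in 10 of 13 (11 adjusted over the list alone), including CXCL1 and IL6 by 1.47 each (adjusted p = 1.1e-06, and adjusted p = 0.102 with an estimated correlation). Untreated levels of CXCL1 and IL6 were 0.03 ± 0.06 and 0.17 ± 0.13 FPKM, so their fold changes depend on the pseudocount. Glucocorticoid-responsive genes rose in 7 of 11 and fell in 2 (8 and 2 adjusted over the list alone), with CEBPD up by 1.46 ± 0.13 and FKBP5 by 1.37 ± 0.12 (adjusted p = 0.00019, and adjusted p = 0.102 with an estimated correlation). Oxidative stress genes of the NRF2 list rose in 8 of 17 and fell in 1 (10 and 1 adjusted over the list alone), with the cystine transporter gene SLC7A11 up by 1.37 ± 0.12 and SRXN1 by 1.31 ± 0.13 (adjusted p = 0.00068, and adjusted p = 0.393 with an estimated correlation).

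Of 20 circadian clock genes 13 fell and 3 rose at 4 h (14 and 3 adjusted over the list alone), with a median of -0.48 (adjusted p = 0.00038, and adjusted p = 0.124 with an estimated correlation). The clock output genes TEF and DBP changed by -1.63 ± 0.12 and -1.27 ± 0.15, and the repressor genes CRY2 and CRY1 by -1.16 ± 0.09 and 1.03 ± 0.11. Basement membrane genes fell in 13 of 28 and rose in 3 (15 and 3 adjusted over the list alone), with fibronectin FN1 at -1.18 ± 0.23 and the collagen gene COL4A2 at -0.62 ± 0.12 (adjusted p = 0.0046, and adjusted p = 0.54 with an estimated correlation). The cell cycle inhibitor gene CDKN1C fell from 49.3 ± 2.67 to 12.3 ± 1.55 FPKM and the growth factor receptor gene PDGFRB from 77.0 ± 5.17 to 26.1 ± 3.63 FPKM. Altogether 4239 genes changed at 4 h, 2156 upward and 2083 downward.

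At 6 h, TM4SF1 was at 303 ± 70.2 FPKM, and ANXA1, a phospholipid-binding protein gene, had risen from 75.4 ± 5.74 to 893 ± 179 FPKM (SD, n = 3). The calcium-binding protein gene S100A2 rose by 3.55 ± 0.26 on the log2 scale and the pentraxin gene NPTX2 by 2.93 ± 0.15. NF-kB and inflammation genes rose in 12 of 13 (12 adjusted over the list alone), with SOD2, the mitochondrial superoxide dismutase gene, up by 1.68 ± 0.20 (adjusted p = 5.1e-09, and adjusted p = 0.0436 with an estimated correlation). Heat shock genes rose in 9 of 16 (10 adjusted over the list alone), such as the chaperone genes HSPH1 by 0.83 ± 0.07 and HSP90AA1 by 0.53 ± 0.08 (adjusted p = 0.0014, and adjusted p = 0.263 with an estimated correlation). Cholesterol synthesis genes rose in 11 of 23 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.0022, and adjusted p = 0.657 with an estimated correlation). Clock genes were lower in 12 of 20 and higher in 2 (13 and 2 adjusted over the list alone), with a median of -0.57 (adjusted p = 1.2e-05, and adjusted p = 0.0811 with an estimated correlation). Pigment synthesis genes fell in 5 of 15 (9 adjusted over the list alone), including the melanocyte transcription factor gene MITF at -0.51 ± 0.08 and TRPM1 at -0.70 ± 0.12 (adjusted p = 9.5e-05, and adjusted p = 0.0811 with an estimated correlation). CDKN1C was again low, at 14.1 ± 2.10 FPKM. Of 3368 genes changed at 6 h, 2030 rose and 1338 fell. Without 6 h replicate 2, 2178 changed.

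At 8 h, genes of cholesterol synthesis were higher in 17 of 23 members (20 adjusted over the list alone), with a median log2 fold change of 0.89 (adjusted p = 2.9e-08, and adjusted p = 0.346 with an estimated correlation). DHCR7 rose by 1.07 ± 0.19, MVD by 0.97 ± 0.20 and NSDHL by 0.89 ± 0.16. Genes controlled by the sterol-sensing LXR receptors fell in 6 of 11 and rose in 1 (7 and 1 adjusted over the list alone), with the cholesterol exporter gene ABCG1 down from 12.6 ± 3.00 to 4.00 ± 0.48 FPKM (SD, n = 3) and SCD up by 1.11 ± 0.28 (adjusted p = 0.0097, and adjusted p = 0.101 with an estimated correlation). NF-kB and inflammation genes were higher in 12 of 13 (13 adjusted over the list alone), with a median of 1.03 and ICAM1 up by 0.91 ± 0.12 (adjusted p = 3.7e-10, and adjusted p = 0.0255 with an estimated correlation). Heat shock genes rose in 10 of 16 and fell in 1 (11 and 1 adjusted over the list alone), with HSPH1 at 0.83 ± 0.07 (adjusted p = 2.8e-06, and adjusted p = 0.113 with an estimated correlation). Pigment synthesis genes fell in 7 of 15 (10 lower and 1 higher adjusted over the list alone), with OCA2 down from 12.2 ± 0.55 to 6.33 ± 0.47 FPKM and the melanin enzyme gene DCT at -0.57 ± 0.10 (adjusted p = 5e-06, and adjusted p = 0.0634 with an estimated correlation). RPE ion and nutrient transporters fell in 8 of 17 and rose in 2 (8 and 2 adjusted over the list alone), including the chloride channel gene CLCN2 at -0.77 ± 0.10, the potassium channel gene KCNJ13 at -0.56 ± 0.10 and, upward, SLC12A2 at 0.34 ± 0.06 (adjusted p = 0.0072, and adjusted p = 0.346 with an estimated correlation). LRAT, the enzyme that esterifies retinol in the visual cycle, fell from 9.42 ± 0.80 to 3.32 ± 0.30 FPKM, and the chromatin protein gene HMGA1 rose from 28.0 ± 4.36 to 194 ± 25.7 FPKM. Of 2837 genes changed at 8 h, 1686 rose and 1151 fell.

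**Figure D1:**
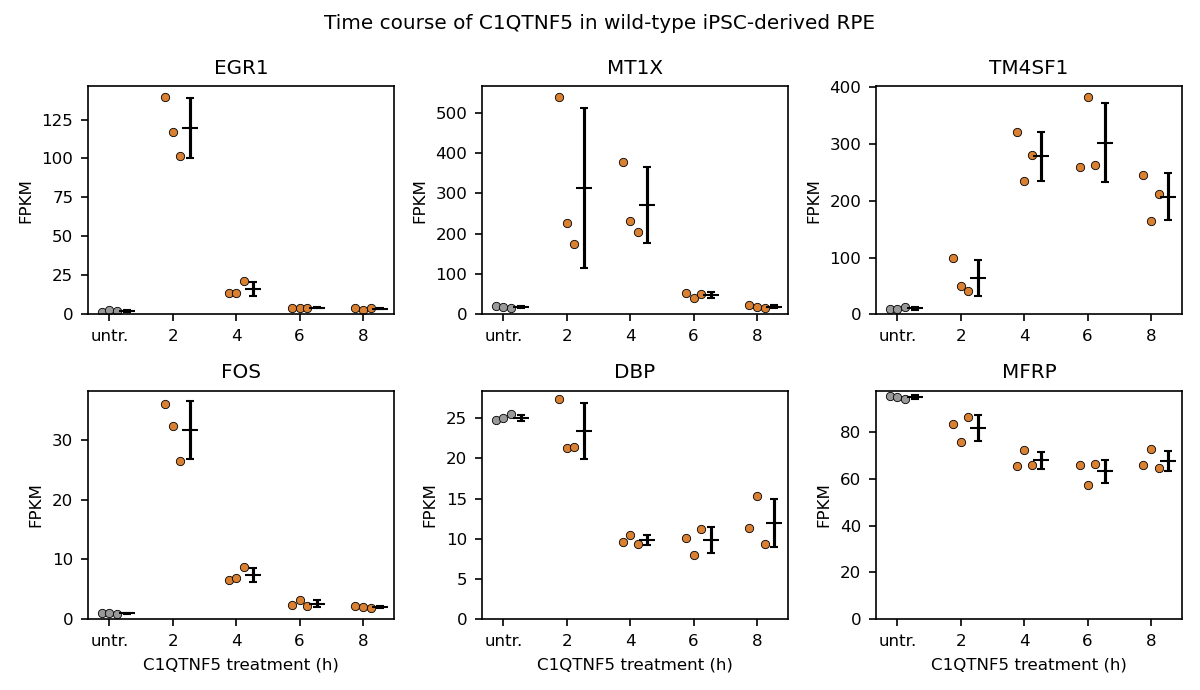
FPKM of 6 genes in the time course (vertical axes, each starting at 0) by hours of C1QTNF5 treatment. Points are the 3 libraries of each group, and the bars beside them are the mean and SD. EGR1 averaged 119.5 FPKM at 2 h and 3.66 FPKM at 8 h, while TM4SF1 averaged 207 FPKM at 8 h and MFRP fell from 95.0 to 67.8 FPKM.

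**Figure D2:**
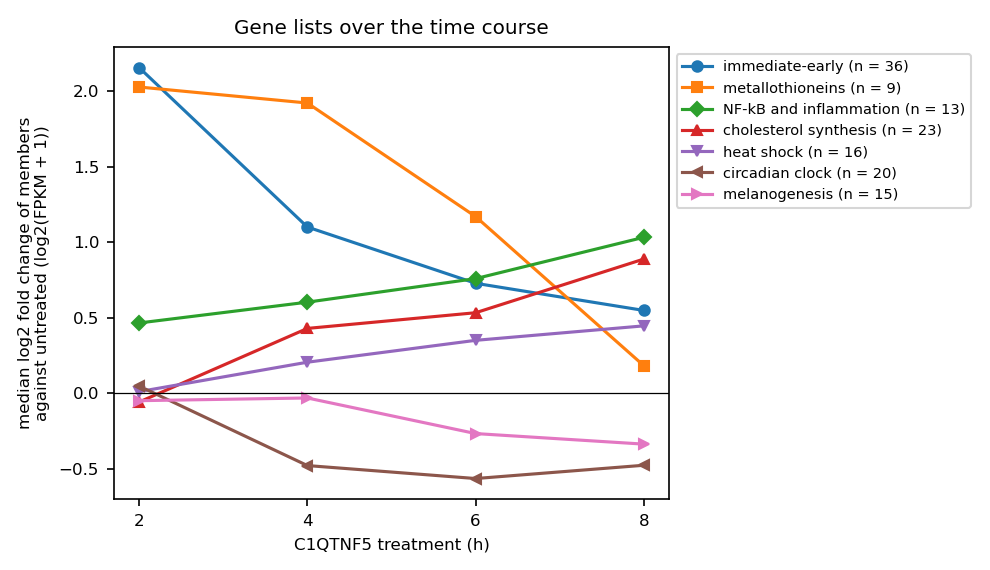
Median log2 fold change of the measured members of 7 gene lists against untreated (vertical axis) at 2, 4, 6 and 8 h (horizontal axis). The number of members is given in the legend, and medians carry no error bar. The immediate-early median was 2.16 at 2 h and 0.55 at 8 h, and the cholesterol synthesis median reached 0.89 at 8 h.

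The comparison of 8 h with 2 h tested how the response moved over time, with a difference that does not involve the untreated means. Immediate-early genes were lower at 8 h in 36 of 36 (36 adjusted over the list alone), with a median of -1.48 (adjusted p = 8.9e-38, and adjusted p = 0.0431 with an estimated correlation). EGR1 was at 3.66 ± 0.60 FPKM at 8 h (SD, n = 3), a log2 change of -4.69 ± 0.16 from 2 h, and MT1X was back at 18.9 ± 3.47 FPKM. Clock genes were lower in 14 of 20 and higher in 2 (14 and 2 adjusted over the list alone), with PER1 at -2.76 ± 0.15 and NR1D2 at -1.15 ± 0.08 (adjusted p = 1.1e-06, and adjusted p = 0.0431 with an estimated correlation). Cholesterol synthesis genes were higher at 8 h in 16 of 23 (16 adjusted over the list alone), led by MVK at 1.36 ± 0.19 and NSDHL at 1.21 ± 0.16 (adjusted p = 6.6e-06, and adjusted p = 0.49 with an estimated correlation). RPE transporters were lower in 10 of 17 and higher in 2 (10 and 2 adjusted over the list alone), including the bicarbonate transporter gene SLC4A5 at -1.01 ± 0.12 and the water channel gene AQP1 at -1.03 ± 0.13 (adjusted p = 0.0021, and adjusted p = 0.317 with an estimated correlation). Late increases included S100A2 at 3.10 ± 0.26, NPTX2 at 2.77 ± 0.15 and the chemokine gene CXCL14 at 2.25 ± 0.16, and SOCS3 was at 21.7 ± 3.51 FPKM after 3.40 ± 0.51 at 2 h. Between 2 and 8 h 4129 genes differed, 2318 higher and 1811 lower at 8 h. Fitting only these 6 libraries, without the spread of the other groups, gave 3282.

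Over the whole time course, 6369 genes changed by the F-test and 6160 at 1 or more of the 4 times. Genes higher at all 4 times numbered 270, and genes lower at all 4 times numbered 81. There were 491 genes up at 2 h and not called at 8 h, and 1339 up at 8 h and not called at 2 h. Across the 14706 genes, which are not independent replicates, log2 fold changes correlated at 0.83 between 6 and 8 h and at 0.33 between 2 and 8 h. The mean over the 6 pairs of times was 0.596. All 4 contrasts share the untreated libraries, and groups without any change that share them gave a mean of 0.498 in 100 simulations. The matching covariance was 0.0866 in the data and 0.0160 in the simulations.

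MFRP (Entrez Gene 83552) and C1QTNF5 (Entrez Gene 114902) had the same FPKM in each of the 27 libraries, with a largest difference of 0, so their transcripts, which come from overlapping transcription units, cannot be read apart in these values. In the time course their FPKM was 95.0 ± 0.81 without treatment (SD, n = 3), 81.9 ± 5.48 at 2 h, 67.9 ± 3.78 at 4 h, 63.3 ± 4.90 at 6 h and 67.8 ± 4.30 at 8 h. By limma the log2 fold changes were -0.21 ± 0.07 at 2 h (adjusted p = 0.088), -0.48 ± 0.07 at 4 h (adjusted p = 0.00025), -0.58 ± 0.07 at 6 h and -0.48 ± 0.07 at 8 h, with each treated library lower than each untreated one. The exact two-sided permutation p was 0.1 at each time, the smallest that 3 against 3 libraries allow.

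In the knockout experiment, the shared value of MFRP and C1QTNF5 was lower in libraries labelled knockout among untreated cells and higher in them among treated cells. Untreated, the libraries labelled knockout were at 34.8 ± 5.18 FPKM and those labelled wild type at 95.8 ± 0.91 FPKM (SD, n = 3), a log2 difference of -1.44 ± 0.11. After 4 h of C1QTNF5, the libraries labelled knockout were at 79.2 ± 8.99 FPKM and those labelled wild type at 28.97 ± 2.00 FPKM, a difference of 1.42 ± 0.11 in the other direction. The exact permutation p was 0.1 for both, the smallest possible. Because a knockout allele can still be transcribed, these RNA levels do not show which libraries lack the protein. All genotype statements that follow use the labels as given.

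**Figure D3:**
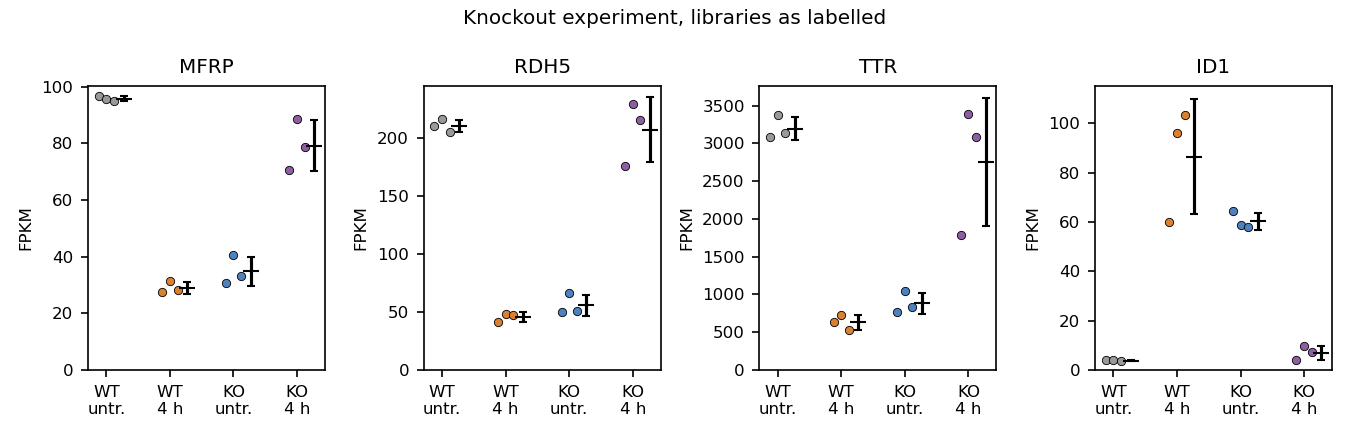
FPKM of MFRP, RDH5, TTR and ID1 (vertical axes, each starting at 0) in the 4 groups of the knockout experiment, as labelled: wild type (WT) and knockout (KO), untreated or after 4 h of C1QTNF5. Points are the 3 libraries of each group, with the mean and SD beside them. MFRP averaged 95.8 and 28.97 FPKM in untreated and treated wild type, and 34.8 and 79.2 FPKM in untreated and treated knockout.

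The untreated genotype comparison asked how libraries labelled knockout differed from those labelled wild type. Whether loss of MFRP caused the differences cannot be told, since culture states that the labels do not record could follow the same groups. Genes of the visual cycle, which regenerates the light-sensitive retinoid, were lower in the libraries labelled knockout in 10 of 13 members (11 adjusted over the list alone), with a median log2 difference of -1.13 (adjusted p = 2.8e-10, and adjusted p = 0.116 with an estimated correlation). The retinol dehydrogenase gene RDH5 was at 55.9 ± 9.03 against 210.9 ± 5.42 FPKM (SD, n = 3), the isomerase gene RPE65 at 6.88 ± 2.39 against 20.7 ± 2.51 FPKM, and the retinol carrier gene TTR at 883 ± 141 against 3196 ± 153 FPKM. RPE transporters were lower in 12 of 17 (13 adjusted over the list alone), including SLC4A5 at -1.78 ± 0.14 and the chloride channel gene BEST1 at -1.71 ± 0.17 (adjusted p = 2.9e-08, and adjusted p = 0.116 with an estimated correlation). RPE identity genes were lower in 13 of 20 and higher in 1 (13 and 1 adjusted over the list alone), with the cation channel gene TRPM3 at -0.78 ± 0.09 (adjusted p = 5.6e-08, and adjusted p = 0.205 with an estimated correlation). Genes linked to macular dystrophy or age-related macular degeneration were lower in 9 of 19 and higher in 2 (12 and 2 adjusted over the list alone), with COL8A1 at -1.28 ± 0.14 and ABCA4 at -1.20 ± 0.14 (adjusted p = 4.7e-05, and adjusted p = 0.116 with an estimated correlation). C1QTNF5 is itself in that list. The largest decrease was in OC90 (Entrez Gene 729330), which encodes an otoconial protein, from 905 ± 59.7 to 84.9 ± 15.5 FPKM.

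Genes of other programmes were higher in the untreated libraries labelled knockout. ID1 (Entrez Gene 3397), an inhibitor of DNA binding that BMP signals induce, was at 60.4 ± 3.45 against 3.81 ± 0.31 FPKM, and ID4 was higher by 3.46 ± 0.17 on the log2 scale. The TGF-beta and BMP target list was higher in 10 of 19 and lower in 1 (11 and 1 adjusted over the list alone), with ID3 at 2.95 ± 0.26 and ID2 at 1.78 ± 0.17 (adjusted p = 2.1e-05, and adjusted p = 0.178 with an estimated correlation). Mesenchymal genes were higher in 11 of 19 (14 higher and 2 lower adjusted over the list alone), with the cadherin genes CDH11 at 1.05 ± 0.09 and CDH2 at 0.60 ± 0.07 (adjusted p = 0.0001, and adjusted p = 0.116 with an estimated correlation). Markers of other cell types moved as well. Retinal progenitor and neuron markers were higher in 10 of 13 and lower in 1 (10 and 1 adjusted over the list alone), such as SNAP25 at 1.38 ± 0.12, PAX6 at 0.88 ± 0.08 and STMN2 at 3.72 ± 0.32 against 0.52 ± 0.40 FPKM (adjusted p = 5e-06, and adjusted p = 0.0321 with an estimated correlation). Markers of ciliary and choroid plexus epithelium were lower in 10 of 13 and higher in 1 (10 and 1 adjusted over the list alone), with the prolactin receptor gene PRLR at -1.32 ± 0.14 and WFIKKN2 at -1.63 ± 0.19 (adjusted p = 7.4e-06, and adjusted p = 0.205 with an estimated correlation). TTR belongs to this list too. Of 2755 genes that differed without treatment, 1566 were higher and 1189 lower in the libraries labelled knockout. The count was 4918 when only these 6 libraries were fitted, 1830 without untreated knockout replicate 1 and 1828 without replicate 3.

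Among the treated libraries, visual cycle, RPE, BMP target, mesenchymal and cell-type marker genes differed in the opposite direction. Visual cycle genes were higher in the libraries labelled knockout in 11 of 13 (11 adjusted over the list alone), with RDH5 at 207 ± 28.1 against 45.8 ± 4.01 FPKM (SD, n = 3) and RGR at 2.04 ± 0.23 (adjusted p = 3.4e-08, and adjusted p = 0.163 with an estimated correlation). RPE identity genes were higher in 14 of 20 and lower in 1 (14 and 2 adjusted over the list alone), with TRPM3 at 1.14 ± 0.09 (adjusted p = 4.1e-07, and adjusted p = 0.202 with an estimated correlation). RPE transporters were higher in 11 of 17 and lower in 1 (12 and 1 adjusted over the list alone), with BEST1 at 435 ± 35.6 against 97.8 ± 6.80 FPKM (adjusted p = 2e-06, and adjusted p = 0.163 with an estimated correlation). TGF-beta and BMP targets were lower in 13 of 19 and higher in 1 (15 and 1 adjusted over the list alone), with ID1 at 7.01 ± 2.86 against 86.6 ± 23.3 FPKM (adjusted p = 9.3e-07, and adjusted p = 0.163 with an estimated correlation). Mesenchymal genes were lower in 12 of 19 (13 adjusted over the list alone), with CDH11 at -1.30 ± 0.09 and VIM at -0.92 ± 0.15 (adjusted p = 2.4e-05, and adjusted p = 0.0881 with an estimated correlation). Retinal progenitor and neuron markers were lower in 9 of 13 and higher in 1 (9 and 1 adjusted over the list alone), with PAX6 at -0.97 ± 0.08 (adjusted p = 0.00018, and adjusted p = 0.0881 with an estimated correlation). Ciliary and choroid plexus markers were higher in 9 of 13 and lower in 2 (10 and 2 adjusted over the list alone), with PRLR at 1.62 ± 0.14 (adjusted p = 0.00014, and adjusted p = 0.21 with an estimated correlation). Metallothioneins were higher in 4 of 8 (5 adjusted over the list alone), with MT2A at 1.41 ± 0.21 (adjusted p = 0.002, and adjusted p = 0.333 with an estimated correlation). Of 3209 genes that differed, 1398 were higher and 1811 lower in the libraries labelled knockout. Without treated knockout replicate 1, 4920 differed. Fitting only these 6 libraries gave 1614.

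**Figure D4:**
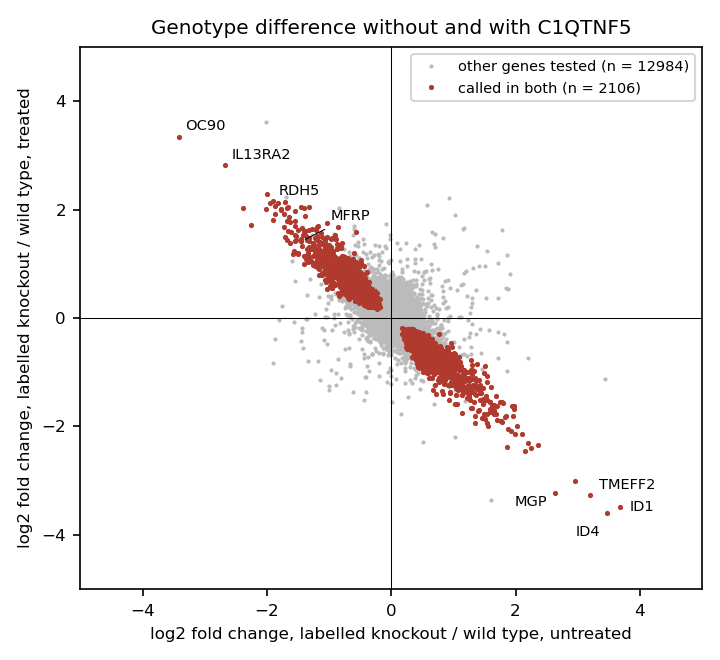
Log2 fold change of libraries labelled knockout over those labelled wild type without C1QTNF5 (horizontal axis) and after 4 h of C1QTNF5 (vertical axis), 1 point per tested gene. The 2106 genes that passed the test in both comparisons, in red, all lie at the upper left (917 genes) or the lower right (1189 genes).

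Set against each other across the 15090 genes, which are not independent replicates, the genotype differences without and with treatment correlated at -0.74 and share no library. Of the 2106 genes called in both, 1189 were higher and then lower, 917 lower and then higher, and 0 had the same sign. Independent calls would give 188 and 110 genes in those classes. For 10 of 13 visual cycle genes, 14 of 20 RPE identity genes, 11 of 17 RPE transporters and 11 of 19 mesenchymal genes, the difference passed the test in both comparisons with opposite signs.

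Among libraries labelled wild type, immediate-early genes were higher and visual cycle genes lower in those treated with C1QTNF5 for 4 h than in untreated ones. Immediate-early genes rose in 22 of 30 and fell in 1 (23 and 1 adjusted over the list alone), including CCN2 by 2.20 ± 0.19 and KLF6 by 1.14 ± 0.08 (adjusted p = 2.4e-09, and adjusted p = 0.118 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 24 (15 higher and 1 lower adjusted over the list alone; adjusted p = 0.00012, and adjusted p = 0.464 with an estimated correlation). Visual cycle genes fell in 10 of 13 (10 adjusted over the list alone), with RDH5 at -2.18 ± 0.13 and TTR at -2.34 ± 0.24 (adjusted p = 1.8e-08, and adjusted p = 0.118 with an estimated correlation). At 4 h of the time course, 4 of these 13 genes rose and 1 fell (5 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.0756). TGF-beta and BMP targets rose in 14 of 19 (15 adjusted over the list alone), with ID1 up by 4.15 ± 0.25 (adjusted p = 2.2e-07, and adjusted p = 0.118 with an estimated correlation). Markers of retinal progenitors and neurons rose in 9 of 13 beside these groups (11 adjusted over the list alone), with PAX6 up by 0.91 ± 0.08 (adjusted p = 7.8e-06, and adjusted p = 0.0398 with an estimated correlation). Ciliary and choroid plexus markers fell in 10 of 13 and rose in 2 (10 and 2 adjusted over the list alone), with PRLR at -1.81 ± 0.14 (adjusted p = 1.3e-05, and adjusted p = 0.169 with an estimated correlation). In total 4234 genes changed, 2500 upward and 1734 downward. MFRP changed by -1.69 ± 0.11. Across 14337 genes tested in both experiments, these changes correlated with the 4 h changes of the time course at 0.27 by Pearson and 0.22 by Spearman. In sign, 67.3% of the genes called in the time course went the same way. With a filter at an FPKM of 5 the Pearson value was 0.313.

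Among libraries labelled knockout, inflammatory, sterol and visual cycle genes were higher in the treated than in the untreated ones, and markers of other cell types differed too. NF-kB and inflammation genes rose in 11 of 12 (11 adjusted over the list alone), with the chemokine gene CCL2 at 15.3 ± 4.49 against 2.52 ± 0.46 FPKM (SD, n = 3) and LIF up by 2.13 ± 0.19 (adjusted p = 5.6e-07, and adjusted p = 0.112 with an estimated correlation). Cholesterol synthesis genes rose in 14 of 24 (16 adjusted over the list alone; adjusted p = 5.6e-07, and adjusted p = 0.356 with an estimated correlation). NRF2 genes rose in 8 of 17 (11 adjusted over the list alone), with SLC7A11 up by 1.76 ± 0.09 (adjusted p = 0.0012, and adjusted p = 0.356 with an estimated correlation). Visual cycle genes rose in 10 of 13 (10 adjusted over the list alone), with RPE65 up by 1.65 ± 0.18 (adjusted p = 6.7e-07, and adjusted p = 0.284 with an estimated correlation). Retinal progenitor and neuron markers fell in 8 of 13 and rose in 2 (9 and 2 adjusted over the list alone), with PAX6 at -0.94 ± 0.08 and STMN2 at -1.64 ± 0.17 (adjusted p = 0.00152, and adjusted p = 0.112 with an estimated correlation). Ciliary and choroid plexus markers rose in 6 of 13 and fell in 2 (7 and 2 adjusted over the list alone), with PRLR up by 1.14 ± 0.14 and WFIKKN2 by 1.27 ± 0.19 (adjusted p = 0.00271, and adjusted p = 0.356 with an estimated correlation). The largest single increase was in TM4SF1, from 3.74 ± 0.73 to 73.0 ± 30.6 FPKM, and the largest decrease in ID4, from 54.9 ± 5.78 to 3.79 ± 1.18 FPKM. Of 3492 genes changed, 1656 rose and 1836 fell. MFRP changed by 1.17 ± 0.11. The count was 1786 when only these 6 libraries were fitted and 5480 without treated knockout replicate 1.

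The interaction tested whether the treatment response differed between the labelled genotypes, as the response in knockout minus that in wild type. Visual cycle genes responded higher in knockout in 11 of 13 (11 adjusted over the list alone), with a median of 2.20, RDH5 at 4.06 ± 0.18 and RPE65 at 3.12 ± 0.25 (adjusted p = 5.8e-09, and adjusted p = 0.148 with an estimated correlation). RPE transporters were higher in 12 of 17 and lower in 1 (13 and 1 adjusted over the list alone), with BEST1 at 3.85 ± 0.25 (adjusted p = 5.2e-07, and adjusted p = 0.148 with an estimated correlation). Mesenchymal genes were lower in 14 of 19 and higher in 1 (15 and 1 adjusted over the list alone), with CDH11 at -2.35 ± 0.13 (adjusted p = 4.3e-05, and adjusted p = 0.102 with an estimated correlation). Retinal progenitor and neuron markers were lower in 10 of 13 and higher in 1 (10 and 1 adjusted over the list alone), with STMN2 at -3.42 ± 0.24 (adjusted p = 5.1e-05, and adjusted p = 0.0667 with an estimated correlation). The interaction passed the test for 4714 genes, 2037 higher and 2677 lower (6924 genes without treated knockout replicate 1), and for MFRP at 2.86 ± 0.15. Responses in the labelled genotypes correlated at -0.40 across genes. Over all 10 comparisons, 153 of 430 list tests passed with the preset correlation and 11 with an estimated one.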

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

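Among the tests named here, the regroupings of the libraries were planned before the data were examined, and all tests of the explanations for the turned genotype difference and for the immediate-early rise were chosen only after the result was seen.

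The response to 4 h of C1QTNF5 differed between the labelled genotypes for 4714 genes and 19 gene lists, by a test of the difference itself. With an estimated correlation between genes, 0 of the lists passed. The response in knockout was higher than in wild type for the otoconial protein gene OC90 (log2 difference 6.76), the decoy receptor gene IL13RA2 (5.50), the tight junction gene CLDN2 (4.41), ADTRP (4.29), the homeobox gene DMBX1 (4.07), the retinol dehydrogenase gene RDH5 (4.06), PRSS33 (4.03), the cathepsin gene CTSF (3.99), the retinol carrier gene TTR (3.94) and the carotene oxygenase gene BCO1 (3.94). It was lower for ID1 (-7.16), ID4 (-7.07), TMEFF2 (-6.47), ID3 (-5.95), the calcification inhibitor gene MGP (-5.87), CPAMD8 (-4.72), NTNG2 (-4.64), DLX3 (-4.52), CHRM4 (-4.24) and PODN (-4.24). MFRP and C1QTNF5, which share their values, differed by 2.86. Of 100 regroupings of the 12 libraries, 1, the real one, gave as many as 4714 genes, and the highest other gave 3691. All group labels were shuffled together, so chance was excluded for differences between the groups. The interaction was not tested apart from genotype and treatment by these regroupings.

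For RDH5, TTR, ID1 and 2106 genes in all, the knockout against wild type difference passed the test both without and with treatment, with opposite signs in each. A common shift of these genes by C1QTNF5 in wild-type cells was argued against by the time course. Each gene was signed by its untreated genotype difference. The signed median 4 h change of the 1943 such genes tested there was -0.02 on the log2 scale (-0.029 to -0.0015 with each library left out). Of them 47.9% kept that sign, so single genes may still respond. In libraries labelled wild type of the knockout experiment the signed median was 0.704, over 2106 genes. Genes and signs were chosen in that experiment, partly from the same untreated libraries, so the choice itself raises the 0.704. A candidate explanation is that the genotype labels were exchanged among the treated libraries. With these labels exchanged, the mean correlation of the treatment contrasts with the 4 h change of the time course gained 0.16 (jackknife SE 0.039). The single values went from 0.265 and 0.344 to 0.498 and 0.432. Exchanging the labels of the untreated libraries instead gives the same contrasts, so the gain alone cannot tell which libraries were exchanged. Each library was also placed on the genes with opposite signs, from 0 at untreated wild type to 1 at untreated knockout. The wild-type time course libraries lay at -0.274 to 0.003, treated knockout at 0.039 to 0.102 and treated wild type at 1.07 to 1.15. If the cells and the scaling of both experiments were alike, these positions argue against an exchange among the untreated libraries. A state of the cells that is unrelated to the 4 h response and follows these groups would bring such a gain in correlation too. Such culture states, which the labels do not record, cannot be told apart from the 4 groups. The mean correlation of untreated knockout with treated wild-type libraries was 0.976, beside 0.964 with untreated wild type. Treated knockout gave 0.962 with untreated wild type and 0.945 with treated wild type. Libraries thus paired across the genotype labels, and the design gives no bound for such states. A response of wild-type cells that loss of MFRP reverses needs these genes to move in wild type in the signed direction. As a set they did not in the time course (-0.02), which argues against it too. No label was changed in the report.

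The change from untreated also differed between 2 and 8 h, for 4129 genes and 15 gene lists, by a test of the difference itself. With an estimated correlation between genes, 2 lists passed. Later transcripts were S100A2 (3.10), NPTX2 (2.77), SOCS3 (2.36), CXCL14 (2.25), AKAP12 (1.98), GALNT9 (1.92), CCN3 (1.92), VGF (1.84), STK32B (1.81) and TM4SF1 (1.77). Earlier ones were the immediate-early genes EGR1 (-4.69), FOSB (-4.54), ARC (-4.47), EGR2 (-3.78), NR4A1 (-3.68), FOS (-3.42) and KLF10 (-2.87), along with MT1X (-3.82), RGCC (-3.0) and NAB2 (-2.93). MFRP and C1QTNF5 differed by -0.27. The 10 splits of these 6 libraries are too few for a share under 0.05, and the highest other split gave 1 gene.

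For the immediate-early rise at 2 h, scaling between libraries was argued against, as the lowest median under the other scalings was 2.17 on the log2 scale. Handling or a change of medium at the time of treatment might raise the same genes. The median of the list was 0.55 at 8 h, but the labels name no vehicle group, so handling and C1QTNF5 cannot be told apart for these genes. The same holds for the other differences between treated and untreated libraries.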

How the results depend on the processing

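Exchanging the genotype labels of the treated libraries and the contrasts of mean treatment and mean genotype response were chosen only after the data were seen, and the other settings were planned.

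No named gene and no described list changed direction under any planned setting. The exchange of genotype labels, which turns the treated genotype difference around by construction, was not run on named genes or described lists. Of 458 named calls, 18 were lost and 4 further genes gained in at least 1 setting. Of 65 described list calls, 54 were lost with an estimated correlation and 0 with other settings or leave-outs. All lists called fell from 153 to 11 with the estimated correlation, and ran from 141 to 163 with each library left out.

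Array weights raised the counts to 4815 at 2 h, 7960 at 4 h, 7211 at 6 h, 6926 at 8 h, 10843 by the F-test, 5780 for untreated genotypes, 6776 and 5892 for treatment in wild type and knockout and 4027 for the mean treatment response. The weights did not reach their tolerance and ran from 0.052 (treated knockout replicate 1) to 20.8 (untreated time course replicate 2). Fits on the compared groups only gave 519 genes at 2 h, 4918 for untreated and 1614 for treated genotypes, and 1786 for treatment in knockout. For both settings the cause was not tested.

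With the treated genotype labels exchanged, 998 genes changed by treatment in wild type, 709 in knockout, 0 in the interaction and 4714 for the mean genotype difference. The last 2 restate the counts of the mean genotype difference and the interaction, which the exchange turns into each other by construction. The correlation between experiments was 0.229 with a pseudocount of 0.1 and 0.313 at an FPKM of 5, and that between times 0.621 at an FPKM of 5; the cause was not tested. The sample number as a replicate block gave 1290, 4098, 3195 and 2691 genes at 2, 4, 6 and 8 h and 4597 for the interaction.

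With each library left out, counts ran from 909 (without untreated replicate 2) to 1468 at 2 h, from 2178 (without 6 h replicate 2) to 3463 at 6 h, from 1828 (without untreated knockout replicate 3; 1830 without replicate 1) to 2374 for untreated genotypes, from 2302 to 4920 for treated genotypes, from 2372 to 5480 for treatment in knockout and from 1346 to 3735 for the mean treatment response. The highest of these last 3 were without treated knockout replicate 1. The mean genotype difference ran from 0 to 1, and the correlation between times from 0.579 to 0.634 (without untreated replicate 3; 0.623 without replicate 1). The largest shift of the share of higher calls by a scaling was -9.5 percentage points, at 6 h with quantile normalization. Total depth is unknown, as no counts are given, so what it limits was not computed and a test on counts was not run. Estimated relative depth ran from 0.81 to 1.18 in the knockout experiment and from 0.896 to 1.22 in the time course.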

Other observations

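The mean treatment response and mean genotype difference, the tests on correlations and those on treated knockout replicate 1 were chosen only after the result was seen; the other splits were planned.

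Averaged over both labelled genotypes, which an exchange of genotype labels leaves as it is, 1909 genes differed after 4 h of C1QTNF5. Of these, 1224 were higher and 685 lower in treated libraries, and the count was 3735 without treated knockout replicate 1. TNFRSF12A, the receptor of TWEAK, rose by 2.87 ± 0.19 on the log2 scale, TM4SF1 by 2.85 ± 0.17 and the vitamin D hydroxylase gene CYP24A1 by 2.68 ± 0.13. Immediate-early genes rose in 20 of 30 (23 adjusted over the list alone; adjusted p = 0.0885 with an estimated correlation), cholesterol synthesis genes in 15 of 24 (18 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation) and NF-kB genes in 9 of 12 (10 adjusted over the list alone; adjusted p = 0.0829 with an estimated correlation). Hypoxia genes fell in 8 of 21 (14 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). These changes correlated with the 4 h changes of the time course at 0.54 across genes. Of 100 regroupings, 1, the real one, gave as many genes, and the highest other gave 432. These regroupings shuffled genotype and treatment together, so they exclude chance for differences between the groups, not for treatment alone. The genotype difference averaged over both treatments passed the limma test for 0 genes, with 669 at an unadjusted p under 0.05. Of 43 gene lists 9 passed for this difference (2 higher and 7 lower), and 0 with an estimated correlation. As the real count of genes was 0, all 100 regroupings reached it by definition, so this comparison with chance decides nothing. The highest regrouping gave 3567 genes, which points to a structure of the samples, such as the interaction of 4714 genes.

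The F-test over the time course gave 6369 genes and the highest other regrouping 709, with 1 of 100 as high, the real one, so chance was excluded. For list calls at the preset correlation the real count was 153, with 1 of 100 regroupings as high, the real one. The highest other gave 142, so the count does not show that single list calls lie beyond chance. With an estimated correlation 11 lists passed, and that count was not compared with regroupings. The correlation between time points was 0.596, and 17 of 100 regroupings were as high, up to 0.747, so chance was not excluded. For the 3 against 3 comparisons and the correlation between experiments, the 10 splits are too few for a share under 0.05. The real counts were 1375, 4239, 3368 and 2837 at 2, 4, 6 and 8 h, 2755 for untreated genotypes and 4234 for treatment in wild type, each with 1 gene in the highest other split. They were 3209 for treated genotypes and 3492 for treatment in knockout, with 2 and 4 genes in the highest other split. The correlation between experiments was 0.265 and the highest other 0.195.

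Treated knockout replicate 1 correlated at 0.935 with its group. Its deviation from replicates 2 and 3 correlated with transcript length at 0.294 by Spearman, while the largest value among the 9 libraries of the other groups was 0.075. In the time course the values reached 0.333 in size, in 6 h replicate 3. There the median deviation was 0.092 in the bottom quartile of transcript length and -0.067 in the top quartile. In treated knockout replicate 1 these medians were -0.236 and 0.212, a larger shift. A bias linked to transcript length therefore stays open as what sets treated knockout replicate 1 apart. A mixture with the untreated knockout group was argued against, as 5.2% of the variance of the deviation lay along the difference to that group. The slope along it was 0.322, and it was 0.354 and 0.329 for replicates 2 and 3 tested alike. On 416 genes that part the untreated groups, from 0 at wild type to 1 at knockout, replicate 1 lay at 0.162 and replicates 2 and 3 at 0.0602 and 0.137. No biological explanation was tested.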
